A study of Mus musculus with 6 samples.

How the data were processed

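RNA was pooled from 4 cochleae per sample, and 3 pools of each genotype were hybridised as biotin-labelled cRNA, 1 Affymetrix array per pool, per the labels. The deposited table holds 1 log2 value per probe set and array for 22690 probe sets; the log base is inferred from the range of the values, and the summarisation method and background correction are not given in the sources used here. Values run far below 0, so no floor or offset was in place, and signal near the bottom of the range varies widely on the log2 scale. The deposited values were not on a common scale: array medians ran from 5.61 to 6.36, and upper and lower quantiles shifted by different amounts.

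Groups were taken from the sample titles, which give the genotype and a replicate number. The descriptions give the same genotypes as the titles, while another label field carries the wild type sign for the 3 null samples, and 1 wild type sample has a slightly different age in that field. The titles also carry a number, 14 for replicate 1 of each genotype and 16 for replicates 2 and 3, whose meaning is not given. No 2 arrays held identical values, and correlations between arrays across probe sets ran from 0.939 to 0.960.

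The design written before the data were examined assumed a normalized table and a fit on the values as deposited. Because the table turned out not to be normalized, the arrays were quantile normalized before any fit, an alternative that had been listed beforehand, and the fit on the deposited values is reported beside the counts. The 64 control probe sets were left out and no filter on level was applied. Of the 22626 probe sets tested, 20380 were annotated to 1 gene, 691 to several and 1555 had no gene named in the platform annotation used. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, in which 29 single-gene probe sets had no match and no symbol changed. No coordinates are given, since the annotation and the table need not share a build. Each of the 12393 genes was represented by its probe set with the highest mean over all 6 arrays, and probe sets of several genes were left out of gene-level tests.

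Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype only, two-sided), with Benjamini-Hochberg adjustment over all probe sets or genes and a threshold of 0.05. Of 31 gene lists fixed at the same stage as the design, 30 were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists, and the sex-linked list was read gene by gene. Camera with an estimated correlation and fry were run beside it. Of 557 list members 487 were measured, and a list needed 3 measured members. For single values an exact permutation test over all splits of the arrays was used, whose smallest two-sided p is 0.1. Because 1 list was taken from what the published study reported on these samples (the MEF2 family and Foxm1), it is not independent of them.

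Genes named in the text followed a rule fixed beforehand: Igf1 at all probe sets; up to 12 genes per direction past the threshold or, where fewer passed, 8 per direction by smallest p, given as values only; 4 members of each list past the threshold by smallest p; all MEF2 and Foxm1 genes; 3 members of the insulin-like growth factor, hair cell, neuron and cartilage lists; and the sex-linked genes. No gene without a usual symbol stood ahead of those named by smallest p. Genes outside this rule (Gh, Pomc, Cga, Tshb, Sftpc and other lung genes, Col10a1, Acp5, Ttr, Ctsc, Mpo, Oc90, Hmx3, Myo6 and Myo7a) were chosen after their values were seen.

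The procedure was tested on simulated data of 12393 genes with 200 changed genes in each of 20 simulations. Of genes above the median level, 4.82% were called at 1.5-fold, 51.4% at 2-fold and 90.9% at 4-fold, and of genes below it 0.945%, 9.00% and 36.2%. Simulated genes were independent of each other, so the simulations say nothing about correlation within lists. Alternatives comprised the deposited values, median centring, the replicate number or the title number as a block, a trended and robust variance model, array weights (statmod 1.5.0), the mean over the probe sets of a gene, a filter at the 40th percentile of mean level, other thresholds, and leaving out each array in turn. Chosen after the data were seen were a pseudocount of 32 on back-transformed values, the mean of the Y-linked probe sets as a covariate, leaving out the 2 arrays of title number 14, and the deposited values with the filter.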

Results

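Gene expression was measured in cochleae of mouse embryos at embryonic day 18.5 that carried either the intact Igf1 gene or 2 null alleles of it. Igf1 encodes insulin-like growth factor 1, a secreted growth factor that acts through the receptor Igf1r. Each of the 6 samples was RNA pooled from 4 cochleae, taken with the surrounding otic capsule and without the vestibular organs, and was hybridised to 1 single-colour Affymetrix array. There were 3 independent pools of wild type embryos and 3 of Igf1 null embryos, all on a C57BL/6J background. The deposited log2 signals had array medians of 6.30, 6.30 and 6.09 in wild type replicates 1 to 3 and 5.61, 6.36 and 6.20 in null replicates 1 to 3. The number of arrays limits the precision of every value below, and levels are log2 signals after quantile normalization, with differences given as null minus wild type.

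Igf1 signal was lower in each null pool than in each wild type pool at all 3 probe sets of the gene. At the brightest probe set, which lay at the 98.2 percentile of gene levels, Igf1 averaged 11.05 ± 0.08 (SD, n = 3) in wild type and 10.59 ± 0.13 (SD, n = 3) in null cochleae. The largest difference was at the probe set with means of 8.05 ± 0.11 (SD, n = 3) and 7.06 ± 0.12 (SD, n = 3), where Igf1 differed by -0.99 ± 0.12 (SE), 0.502 of the wild type level. At the dimmest probe set the means were 7.47 ± 0.09 (SD, n = 3) and 6.93 ± 0.22 (SD, n = 3). The exact permutation test, two-sided, gave p = 0.1 for each probe set, the smallest value that 3 against 3 arrays allow. In limma the unadjusted p was 0.0116 for the brightest, 3.7e-04 for the middle and 0.0142 for the dimmest Igf1 probe set, and none passed adjusted over all probe sets (0.887, 0.600 and 0.889). Signal in the null pools was 0.729 of the wild type level at the brightest and 0.684 at the dimmest probe set. The labels do not say which part of Igf1 was disrupted. Signal that remained in the null pools at a probe set outside that part would not bear on the genotype. Whether the 3 probe sets lie outside it is not known here. Since another label field carries the wild type sign for the null samples, these values do not settle the genotype of the pools.

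**Figure D1:**
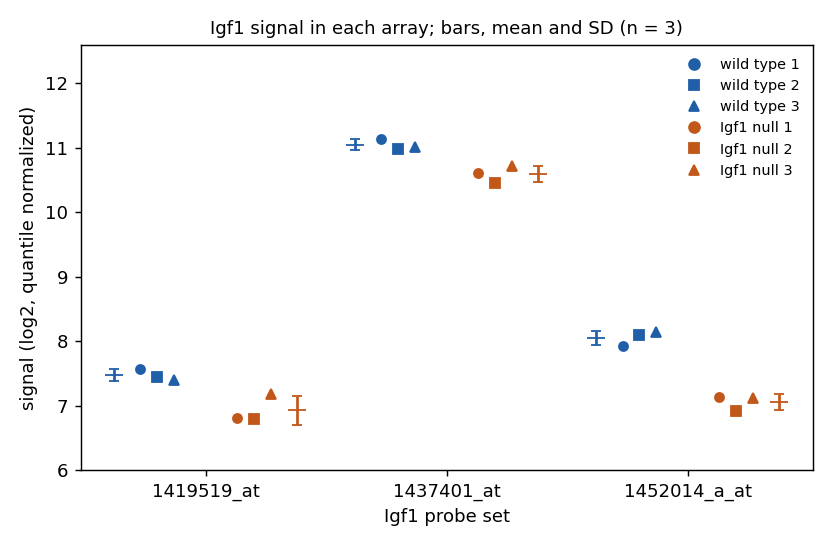
Igf1 signal (vertical axis, log2 after quantile normalization) at its 3 probe sets (horizontal axis) in each of the 6 arrays, blue for wild type and orange for Igf1 null, with the replicate shown by the marker and the mean and SD of 3 arrays beside the points. At the probe set with the largest difference the null arrays lie between 6.92 and 7.14 and the wild type arrays between 7.93 and 8.14.

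Which genes differ between cochleae with and without Igf1 was the question the design poses. With limma, 0 of 22626 probe sets and 0 of 12393 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.307 for probe sets and 0.221 for genes. At an unadjusted p under 0.05 there were 1130 probe sets, where chance alone gives 1131.3, and 612 genes, where chance gives 619.65. The 1130 probe sets comprised 547 with higher and 583 with lower signal in the null pools. With the values as deposited the counts past the adjusted threshold were again 0 and 0 in limma, with 828 probe sets and 419 genes at an unadjusted p under 0.05. Those 828 probe sets comprised 210 with higher and 618 with lower signal, on a scale where the median probe set differed by -0.15 between the groups, against 0.0041 after quantile normalization.

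Because no gene passed the threshold, the genes with the smallest p are given as values. For 13 of the 16 neither group mean lay above the range of Y-linked probe sets in the 3 arrays lowest in Y-linked signal. That range had a median of 0.489 and reached 3.87, a reading of Uty in null replicate 1. Background of other probe sets was not measured. The differences of these 13 genes are between values not above this measure of background and do not show a change in expression. Slc4a1 and Prf1 were above that range in wild type but not in the null pools (means 3.43 and 2.41), so the size of their differences is not determined, and Ifi27l2a was above it in both. With the larger value in the null pools these were Gpr50, a receptor related to the melatonin receptors (2.68 ± 0.21 SE), the homeobox gene Six6 (3.61 ± 0.31), the secreted trypsin inhibitor Spink1 (2.44 ± 0.28), the interferon-inducible gene Ifi27l2a (0.97 ± 0.12), Dppa2 (2.00 ± 0.25), the cathepsin gene Cts8 (3.85 ± 0.49), the lysophosphatidic acid receptor gene Lpar3 (2.32 ± 0.34) and the protamine gene Prm1 (1.44 ± 0.22). With the larger value in the wild type pools these were Trap1a (-3.97 ± 0.30 SE), Slc4a1, which encodes the anion exchanger of red blood cells (-1.76 ± 0.18), Bloc1s4 (-1.78 ± 0.20), the perforin gene Prf1 (-1.59 ± 0.21), the steroid dehydrogenase gene Hsd17b3 (-3.23 ± 0.43), the calcium channel gene Cacna1f (-2.56 ± 0.36), Msmb (-2.73 ± 0.40) and the Toll-like receptor gene Tlr6 (-2.86 ± 0.42). Adjusted p ran from 0.221 for Gpr50, Six6 and Trap1a to 0.629 for Lpar3, Prm1, Cacna1f, Msmb and Tlr6. All 16 lay below the median gene level of 6.64, with a median level of 1.57. Ifi27l2a was the brightest of them, with means of 5.08 ± 0.11 (SD, n = 3) and 6.05 ± 0.12 (SD, n = 3). Without null replicate 3, Hsd17b3, a gene within that background range, alone passed the threshold (-3.75, adjusted p = 0.0213 in limma). The mean over the probe sets of Dppa2 differed by -0.07, against 2.00 at its brightest probe set.

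Skeletal genes of the otic capsule, the cartilage and bone that encloses the cochlea, had lower signal in the null pools. Of 22 measured cartilage genes, 20 were lower and 2 higher, with a median difference of -0.28. Matrilin gene Matn3 differed by -0.93 ± 0.22 (SE), the type IX collagen genes Col9a1 and Col9a3 by -0.26 ± 0.12 and -0.49 ± 0.27, and the chondromodulin gene Cnmd by -0.29 ± 0.16. All 12 measured osteoblast and bone matrix genes were lower, with a median of -0.32, among them Dmp1, a matrix protein gene of osteocytes (-1.52 ± 0.36), Sparc (-0.32 ± 0.12), the type I collagen gene Col1a2 (-0.23 ± 0.10) and the osteoblast transcription factor gene Sp7 (-0.28 ± 0.13). In limma's camera test with its preset correlation the adjusted p was 4.5e-04 for cartilage and 2.1e-04 for bone, and with an estimated correlation the adjusted p = 0.689 and 0.679. No member passed adjusted over all genes, and none adjusted over the list alone. The cartilage median was -0.12 without null replicate 1 (adjusted p = 0.132) and -0.16 without wild type replicate 3 (0.0409). With both arrays of title number 14 left out it was -0.23 (2.4e-04). The bone median was -0.20 without null replicate 3 (0.0411), -0.49 without null replicate 1 (4.3e-07) and -0.48 without title number 14 (1.7e-06).

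Genes of hypoxia and glycolysis were also lower as a group, 16 of 17 measured members, with a median of -0.22. They included the glycolytic enzyme genes Pgk1 (-0.27 ± 0.11 SE) and Pgam1 (-0.23 ± 0.11), the angiogenic factor gene Vegfa (-0.98 ± 0.38) and Bnip3, a mitochondrial protein gene induced by low oxygen (-0.23 ± 0.09). In 8 of these 17 genes the null and wild type arrays did not overlap, where chance gives 10%, and lists that did not pass had about as many, 7 of 17 ribosomal protein genes and 7 of 19 S phase genes. Of 20 immediate early genes, which respond within minutes to growth factors, 17 were lower, with a median of -0.26, among them Ccn2 (-0.45 ± 0.12), Ier3 (-0.33 ± 0.13), Jun (-0.49 ± 0.22) and Nr4a1 (-0.34 ± 0.18). The camera adjusted p was 3.9e-05 for hypoxia and glycolysis and 3.3e-04 for immediate early genes, and with an estimated correlation the adjusted p = 0.635 for both. No member of either list passed adjusted over all genes or adjusted over the list alone. The immediate early median was -0.16 without null replicate 3 (adjusted p = 0.0147), -0.15 with a pseudocount of 32 (8.6e-05), -0.45 with the values as deposited (7.6e-04) and -0.39 without title number 14 (3.8e-06). That of hypoxia and glycolysis was -0.35 with the values as deposited (0.00354).

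Erythroid, endothelial and G2 and M phase genes were the other groups past the threshold as lower. Of 11 measured erythroid genes 6 were lower and 5 higher, with a median of -0.21. The list was dimmer than any other tested, with a median level of 2.26, and its median was -0.016 with a pseudocount of 32 (adjusted p = 0.0485). Slc4a1, with a null mean not above background, stood at -1.76 ± 0.18 (SE), Ermap, with means not above background (3.23 and 1.90), at -1.33 ± 0.35, Alas2, the enzyme gene of heme synthesis in red cells, at -0.79 ± 0.23, and Fech, the last enzyme of that pathway, at -0.21 ± 0.12, or 0.31 with the mean of its probe sets. Of 15 endothelial genes 13 were lower, with a median of -0.11, including Tie1 (-0.25 ± 0.12), Sox17 (-0.23 ± 0.12), Sox18 (-0.23 ± 0.13) and Ramp2 (-0.23 ± 0.14). Of 23 genes of the G2 and M phases of the cell cycle 19 were lower, with a median of -0.08, including Aurkb (-0.32 ± 0.16), Hmmr (-0.21 ± 0.15), Ube2c (-0.23 ± 0.16) and Ttk (-0.19 ± 0.14). The camera adjusted p was 0.0154 for erythroid genes, 0.0380 for endothelium and 0.0497 for G2 and M phase, and with an estimated correlation the adjusted p = 0.635, 0.689 and 0.689. Adjusted over the list alone, 1 erythroid gene passed (Slc4a1), and over all genes none did. The erythroid call was lost without wild type replicate 1 (median -0.11, adjusted p = 0.121) or null replicate 2 (0.0012, 0.0793), and the median was -0.40 without wild type replicate 3 (0.00226) and -0.45 without null replicate 1 (0.0103). The endothelial call was lost without wild type replicate 2 (median -0.021, adjusted p = 0.475), null replicate 1 (-0.072, 0.103) or null replicate 3 (-0.066, 0.187), and the median was -0.19 without wild type replicate 3 (0.00995). Likewise lost was the G2 and M phase call without wild type replicate 1 (-0.031, 0.299), wild type replicate 3 (-0.096, 0.0685) or null replicate 2 (0.0056, 0.945), and its median was -0.15 without null replicate 1 (1.1e-04), -0.13 without wild type replicate 2 (0.0192) and -0.12 without null replicate 3 (0.0403). On the values as deposited the endothelial (0.215) and G2 and M phase (0.116) calls were lost, as with median centring (0.0769 and 0.107) and with the mean of all probe sets of a gene (0.119 for both). The erythroid call was lost with the mean of all probe sets (0.257), array weights (0.0560) and the Y-linked covariate (0.0724), the endothelial call with array weights (0.317) and the G2 and M phase call with the Y-linked covariate (0.648). Without the arrays of title number 14 the erythroid (0.115) and endothelial (0.0621) calls were lost.

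Hair cell genes were the 1 group past the threshold with higher signal in the null pools. Of 19 measured members 16 were higher and 3 lower, with a median of 0.61. The myosin gene Myo15 differed by 0.83 ± 0.17 (SE) and the Usher syndrome gene Ush1c by 1.48 ± 0.46. Slc26a5, which encodes the outer hair cell motor protein prestin, had group means of -1.20 and 0.74, and the actin bundling gene Espn -0.94 and 0.24. Those 4 means are not above background, by the same Y-linked probe sets, so the differences of 1.93 ± 0.38 and 1.18 ± 0.26 for Slc26a5 and Espn do not show higher expression. The camera adjusted p was 0.00137, and with an estimated correlation the adjusted p = 0.635. No member passed adjusted over all genes, while 3 passed adjusted over the list alone (Slc26a5, Myo15 and Espn). The list median was 0.21 without wild type replicate 2 (adjusted p = 0.0238), 0.38 without null replicate 2 (0.0181), 0.29 with the values as deposited (1.1e-04) and 0.06 with a pseudocount of 32 (0.0399). The list was dim, with a median level of 3.61, and its members above the 40th percentile of gene level were Myo7a and Myo6, which differed by 0.06 and 0.03. Of 7 other probe sets of hair cell genes, 3 were higher, with a median of -0.04. The 4 measured vestibular genes, from tissue left out of the dissection, had a median of 0.68 (camera adjusted p = 0.111), with Oc90 at 0.86 and Hmx3 at 0.66. Vestibular genes passed without wild type replicate 3 (0.71, adjusted p = 0.0353) or null replicate 2 (0.91, 0.0454), and their median was 0.38 without null replicate 3 (0.195), 0.39 with the values as deposited (0.0714), 0.32 with array weights (0.409) and 0.21 with a pseudocount of 32 (0.134).

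**Figure D2:**
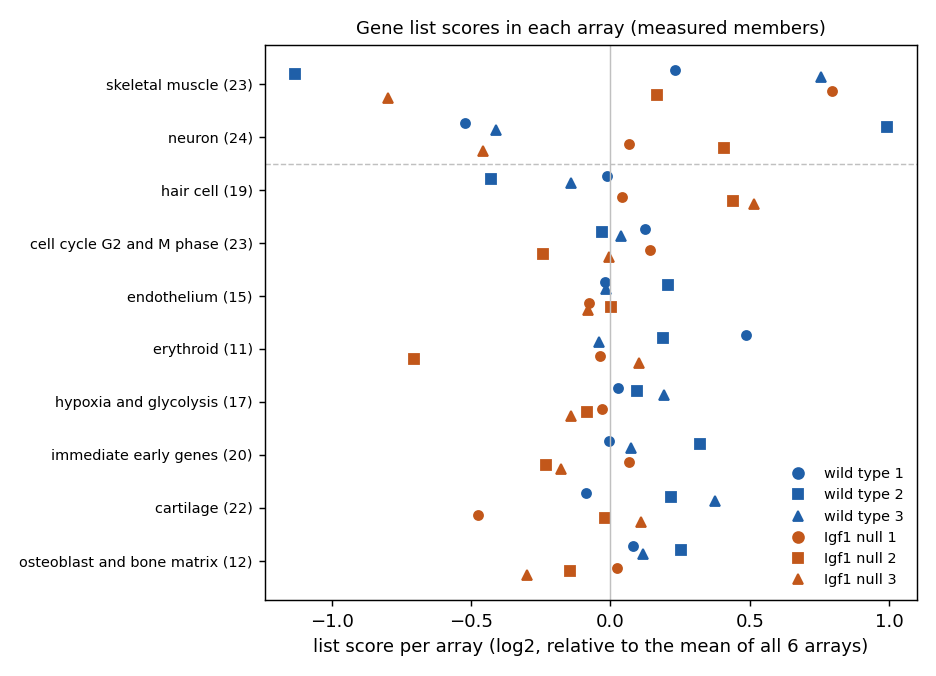
Score of each gene list in each array (horizontal axis, log2: the median over the list's members of the signal minus that member's mean over the 6 arrays) for the 8 lists past the camera threshold with the preset correlation and, above the dashed line, neuron and skeletal muscle genes. Blue points are wild type and orange points Igf1 null arrays, and the number of measured members follows each name. Skeletal muscle scores run from -1.13 in wild type replicate 2 to 0.79 in null replicate 1, a wider range than in the 8 lists below them.

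Of 4 control genes read as signs of RNA quality, beta-actin separated the genotypes, and whether this bears on these 8 lists was not tested. List scores separated the genotypes for bone, hypoxia and glycolysis, and hair cell genes, and overlapped for the other lists past the threshold. Scores of stria vascularis and of ribosomal protein genes, which did not pass, separated the genotypes as well. Chance separates 3 against 3 arrays in 10% of cases, so separation adds no support to the calls. The log2 signal of the 3' control probe set of beta-actin minus that of its 5' probe set was 0.76 ± 0.04 (SD, n = 3) in wild type and 0.94 ± 0.12 (SD, n = 3) in null arrays, higher in each null array (exact permutation p = 0.1, the smallest possible). The same difference for Gapdh was 0.25 ± 0.06 (SD, n = 3) and 0.35 ± 0.17 (SD, n = 3), with an exact permutation p of 0.5. For the transferrin receptor it was 3.35 ± 1.06 (SD, n = 3) in wild type and 2.17 ± 1.01 (SD, n = 3) in null arrays, the other direction (exact permutation p = 0.2), and for pyruvate carboxylase 3.33 ± 0.55 (SD, n = 3) and 3.34 ± 1.03 (SD, n = 3). The 8 calls rest on the preset correlation, as 0 of 30 lists passed with an estimated correlation and 0 with fry.

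The insulin-like growth factor and insulin system, the pathway of the deleted gene, did not pass as a group. Of 26 measured members 10 were higher and 16 lower, with a median of -0.08 and a camera adjusted p of 0.197. The insulin receptor gene Insr stood at -1.86 ± 0.45 (SE) with means not above background (3.13 and 1.27), Igf1 at -0.46 ± 0.11 and the receptor substrate gene Irs2 at 0.99 ± 0.50. No member passed adjusted over all genes or adjusted over the list alone, and the list passed without null replicate 3 (median -0.15, adjusted p = 0.0317) and with the Y-linked covariate (-0.13, 0.0293). Its median was 0.011 without null replicate 1 (0.905). Genes that respond to FoxO factors, which insulin-like growth factor signalling restrains, had a median of -0.08 over 17 members (adjusted p = 0.418). With single arrays left out it ran from -0.17 (without wild type replicate 2) to -0.017 (without wild type replicate 1). The FoxO median was 0.029 with the Y-linked covariate.

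The MEF2 transcription factors and the cell cycle factor Foxm1, with which the published study was concerned, did not pass as a group (5 members, median -0.04, mean -0.30, camera adjusted p = 0.526). Mef2a differed by -0.06 ± 0.09 (SE), Mef2c by -0.04 ± 0.14, Mef2d by -0.03 ± 0.12, Mef2b by -1.59 ± 1.04 with means not above background (1.40 and -0.18), and Foxm1 by 0.23 ± 0.23. The 95% intervals ran from -0.30 to 0.18 for Mef2a, from -0.38 to 0.31 for Mef2c, from -0.33 to 0.27 for Mef2d and from -0.35 to 0.82 for Foxm1. With median centring the signs of Mef2a, Mef2c and Mef2d turned (0.0027, 0.02 and 0.01). The list was chosen from what the study reported on these samples and is not independent evidence of a direction, and 0 members passed adjusted over all genes and 0 adjusted over the list alone.

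Neuronal genes were evenly divided, with 12 of 24 members higher and 12 lower, a median of 4.4e-04 and a camera adjusted p of 0.526. The neurotrophin receptor gene Ntrk2 differed by -0.36 ± 0.13 (SE) and the homeobox gene Isl1 by 0.36 ± 0.33, while the proneural gene Neurog1 was not above background (means -1.15 and -2.24). Both the direction and the call of this list turned on single pools: the median was -0.34 without wild type replicate 1 (adjusted p = 0.0228), 0.46 without wild type replicate 2 (6.9e-04) and -0.23 without null replicate 2 (0.0454). It was also -0.32 with the Y-linked covariate (0.00538) and -0.33 without title number 14 (0.0470). Skeletal muscle genes, from tissue beside the cochlea, were alike in this, with a median of 0.07 (0.700) over all arrays, -0.49 without wild type replicate 2 (0.00949), 0.47 without wild type replicate 3 (0.00699) and 0.50 without null replicate 3 (0.0280), and 0.62 with the Y-linked covariate (2.2e-05). The mean over the probe sets of Ntrk2 differed by 0.47.

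Among the other cell types of the cochlea, supporting cell and sensory epithelium genes had a median of 0.14 (camera adjusted p = 0.157), Schwann cell and myelin genes -0.17 (0.131), stria vascularis and ion transport genes -0.13 (0.318), spiral ligament and periotic mesenchyme genes 0.04 (0.285) and melanocyte genes 0.04 (0.424). With single arrays left out these medians ran from 0.051 (without null replicate 3) to 0.18 for supporting cell, -0.26 to -0.049 (without null replicate 1) for Schwann cell and -0.20 to -0.053 (without null replicate 1) for stria genes. Spiral ligament genes ran from -0.040 (without null replicate 3) to 0.12 and melanocyte genes from -0.0087 (without wild type replicate 2) to 0.27 (without wild type replicate 1), with either sign. Osteoclast genes, of the cells that resorb bone, stood at -0.76 (0.111), with 6 of 9 members lower. Central nervous system (-0.04, 0.381), macrophage (0.02, 0.369), neutrophil (0.19, 0.318) and stratified and ciliated epithelium genes (0.09, 0.392) did not pass either, while the neutrophil granule enzyme gene Mpo passed adjusted over the list alone. For macrophage genes the test pointed downward while the median was above 0, and so it did for neuronal genes. Without wild type replicate 2 the median was 0.094 for central nervous system and -0.14 for stratified epithelium genes. Neutrophil genes stood at 2.3e-04 without null replicate 1. The osteoclast median ran from -1.26 without null replicate 1 (adjusted p = 2.1e-05) to -0.18 without null replicate 2 (0.407), with -0.76 without wild type replicate 3 (0.0490), -0.38 without wild type replicate 1 (0.458) and -0.30 without null replicate 3 (0.393). Osteoclast genes also passed with the values as deposited (0.0258), with the trended and robust variance model (0.0338) and with dim genes left out (0.0239). They passed with both the deposited values and that filter (1.7e-19) and without title number 14 (0.00690). Their median was -0.21 with a pseudocount of 32 (0.111) and -0.30 with the Y-linked covariate (0.440). With both the deposited values and that filter, limma pooled the gene variances to a common value. Adjusted p values of that setting therefore understate the spread of variable genes such as the osteoclast gene Acp5. Also passing were macrophage genes without null replicate 1 (-0.14, 0.0224) and Schwann cell genes without wild type replicate 1 (-0.25, 0.0248), with the Y-linked covariate (-0.30, 0.0240) or with the deposited values and dim genes left out (-0.26, 0.0468). Without null replicate 2, supporting cell (0.17, 0.0450), central nervous system (-0.31, 0.0454) and neutrophil genes (0.73, 0.0327) passed, and without title number 14 supporting cell (0.16, 0.0470) and stratified epithelium genes (0.30, 0.0470) did. As deposited, where all probe sets shifted by -0.15 at the median, the medians of supporting cell and stratified epithelium genes were below 0 (-0.094 and -0.057). So were those of melanocyte (-0.14), neutrophil (-0.072) and macrophage genes (-0.16).

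Of the cell state lists, S phase genes had a median of 0.06 (camera adjusted p = 0.131), apoptosis genes 0.02 (0.424), heat shock genes 0.07 (0.700), cholesterol and fatty acid synthesis genes -0.04 (0.210), oxidative phosphorylation genes 0.02 (0.700) and cytosolic ribosomal protein genes 0.07 (0.285). S phase genes passed without null replicate 2 (0.14, adjusted p = 0.0220) and with the Y-linked covariate (0.12, 0.00604), and their median was -0.088 on the values as deposited. Also passing were oxidative phosphorylation genes without null replicate 3 (0.14, 0.00202) and cholesterol genes without null replicate 2 (-0.18, 0.0327) or wild type replicate 3 (-0.09, 0.0356). With the values as deposited and with median centring, ribosomal protein genes passed as well (0.07, adjusted p = 0.00872, and 0.24, 9.6e-05). Without null replicate 1 the medians of S phase (-0.024), heat shock (-0.035) and oxidative phosphorylation genes (-0.030) were below 0. The sign also turned for apoptosis genes without wild type replicate 2 (-0.054) and for cholesterol genes without null replicate 3 (0.069).

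Sex-linked genes differed between pools of the same genotype. Xist, transcribed from the inactive X chromosome, read 12.23, 10.38 and 12.29 in wild type replicates 1 to 3 and 12.24, -3.93 and 11.91 in null replicates 1 to 3. The Y-linked gene Eif2s3y read -3.56, 6.92 and -0.52 in the wild type and 2.32, 7.33 and 6.80 in the null arrays. Kdm5d read 1.09, 5.16 and 0.55 against 3.11, 5.61 and 5.43, and Uty 3.19, 4.76 and 3.53 against 3.87, 4.81 and 4.40. None of them passed between genotypes (adjusted p = 0.998 in limma for each). Genes of other organs also differed between pools. The lung surfactant gene Sftpc read 12.24 in wild type replicate 1 and between 3.93 and 8.31 in the other 5 arrays. The growth hormone gene Gh read 12.58 in null replicate 2, -5.60 in null replicate 1 and between 7.09 and 7.64 in the remaining arrays. Without wild type replicate 1, 0 probe sets and 0 genes passed in limma, and 8 lists did, of which 6 were among the 8 of all arrays: erythroid and G2 and M phase genes were lost, and neuronal and Schwann cell genes were gained.

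**Figure D3:**
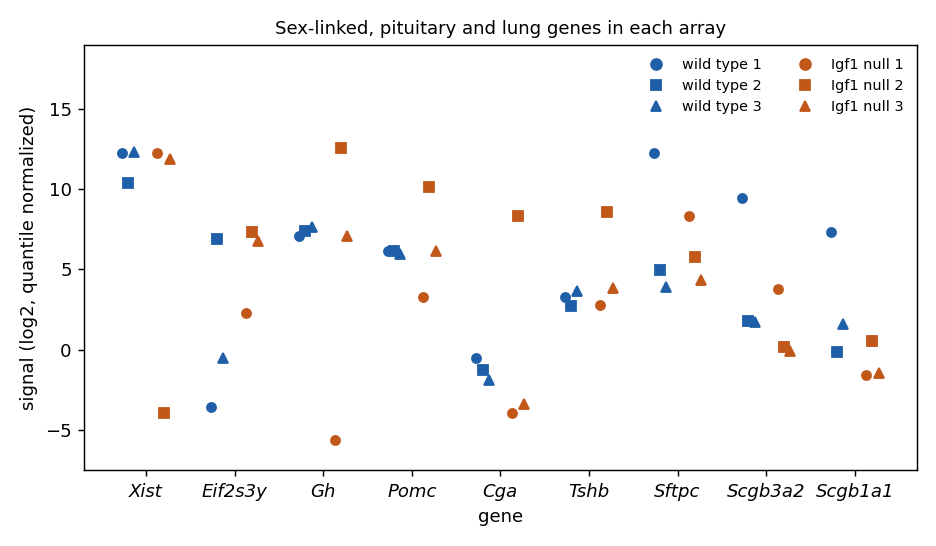
Signal (vertical axis, log2 after quantile normalization) of sex-linked genes (Xist, Eif2s3y), pituitary genes (Gh, Pomc, Cga, Tshb) and lung genes (Sftpc, Scgb3a2, Scgb1a1) in each of the 6 arrays, blue for wild type and orange for Igf1 null, with the replicate shown by the marker. Null replicate 2 stands at -3.93 for Xist and 8.32 for Cga, and wild type replicate 1 at 9.48 for Scgb3a2.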

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

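The pseudocount, the Y-linked covariate, the arrays without title number 14 and the deposited values with dim features left out were tests chosen after the data were seen. Probe sets and genes past the threshold numbered 0 under each setting run except those named next. The deposited values with dim features left out gave 13 probe sets and 5 genes (Xist, Gh, Col10a1, Acp5 and Ctsc). There limma pooled all variances to a common value (54300 total degrees of freedom for probe sets, against 5.32), and 11 of the 13 probe sets lay above the 98th percentile of spread within groups. An unadjusted p under 0.01 in limma with 1.5-fold gave 227 probe sets and 116 genes. Chance gives 226.26 and 123.93 at that p without the fold limit, so these counts are no sign of changed genes. With each array left out in turn there were 0 probe sets, 0 to 1 genes (Hsd17b3 without null replicate 3) and 8 to 13 lists, 13 without null replicate 2. Of the 8 lists, 0 passed with an estimated correlation, 0 with fry and 5 with the mean of all probe sets of a gene. Elsewhere 6 to 11 lists passed, with 5 to 8 of the 8 among them. Hypoxia and glycolysis, bone, immediate early and hair cell genes lost their call only with an estimated correlation and fry; the dim filter left too few hair cell, erythroid, vestibular and neutrophil genes to test.

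With the replicate number as a block, 0 probe sets, 0 genes and 9 lists passed, the 8 and vestibular genes. Arrays of like number correlated by 0.04, 0.10 and 0.02 across all probe sets and were not treated as paired; across brighter probe sets the values were 0.19, 0.38 and 0.14, which differs in verdict, and the blocked counts were seen in the same output. Across the brighter probe sets every array correlated best with its own number, across all probe sets wild type replicate 3 did not, a hint from the data and not the design.

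Of 62 named genes 54 kept their direction under each alternative that gave a value. Most of the 62 were named for a small p in these same arrays, so this count does not measure robustness. With median centring Mef2a stood at 0.0027, Mef2c at 0.022 and Mef2d at 0.012. With the mean of all probe sets Dppa2 stood at -0.071, Fech at 0.31, Mef2a at 0.13 and Ntrk2 at 0.47. Mef2c was 0.013 with the Y-linked covariate and Foxm1 -0.039 without title number 14. With each array left out, G2 and M phase genes ran from -0.15 to 0.0056 (without null replicate 2), Mef2c from -0.14 to 0.068 (without null replicate 3), Mef2d from -0.094 to 0.062 (without wild type replicate 3) and Xist from -7.60 to 0.44 (without null replicate 2). For these reversals the cause was not tested. Dim genes were called less often: in simulations 36.2% of 4-fold changes below the median level were called, against 90.9% above it. The simulations used each gene's own spread and the full change at every level, so they do not measure loss of signal to background.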

Other observations

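The tests of tissue share, of the genes on X and Y, and of the splits for probe sets and genes past the threshold were chosen after the result was seen, as were the genes named in the next paragraph; for tissue share, pituitary and interferon genes the condition for leaving the question open was set after the value was seen.

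Several genes differed more between pools of 1 genotype than between genotypes. Col10a1, the collagen of hypertrophic cartilage, read -0.92 in null replicate 3 and between 6.79 and 8.48 in the other 5 arrays. Acp5, an enzyme gene of osteoclasts, read 8.39, 7.77 and 7.50 in wild type and 8.57, 5.44 and 3.40 in null replicates 1 to 3. Ttr, the transthyretin gene of choroid plexus and liver, read 12.37 in wild type replicate 1 and between 8.92 and 10.65 elsewhere.

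Genes with the smallest p were mostly dim: of 136 genes with an unadjusted p under 0.01, against 123.93 by chance, 93.4% lay below the median level. Noise at background level may account for these. Of other probe sets of the same dim genes, 57.4% (95% interval 43.3 to 70.5) moved the same way, near the 58.7% of all other genes. Each gene stood by its brightest probe set, so the others were dimmer still, and this share cannot tell noise from a change. Genes next to Igf1, where a strain variant could lie, had an odds ratio of 0.464 (0.0116 to 2.66), and genes on X and Y 1.61 (0.629 to 3.44), and both intervals are too wide to decide. An effect of Igf1 loss on some of these genes stays open.

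Cartilage and bone genes had lower signal in the null pools. Sex composition as the whole cause would shrink the cartilage median under the Y-linked covariate. It was -0.40 (camera adjusted p = 4.8e-05) with the covariate against -0.28 without it, which met the bound set against that cause. The question is not settled, since the same covariate, fitted to 6 arrays, also moved skeletal muscle genes to 0.62 (2.2e-05). A smaller share of capsule tissue could lower both lists and raise the others. The score averaged over 15 other cell type lists differed by 0.0685 ± 0.0476 (SE), which met the bound set for that cause. Osteoclast genes were left out of that average together with cartilage and bone genes. Their score was 0.416 in wild type and -0.416 in null pools, and an average that includes them was not computed. The largest rises from wild type to null were in hair cell (-0.19 to 0.33), vestibular (-0.18 to 0.35) and neutrophil scores (-0.16 to 0.18). Median levels of these lists were low (3.61, 5.58 and 4.16). This cause stays open because the exact permutation p was 0.3, and because 5 of those lists had a median difference below 0. Of these, endothelial and erythroid genes passed the camera threshold as lower. Mean scores of neuronal genes (0.0190 in wild type, 0.0065 in null) and macrophage genes (0.079 and -0.019) were lower in the null pools as well. Igf1 loss, the difference the design names, also stays open.

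Lung and pituitary transcripts stood out in single pools. Lung tissue in wild type replicate 1 may be their source there: 12 lung epithelial genes stood there at a median of 3.50 ± 0.844 (SE) above the median of the other arrays, of which the highest value computed likewise was 0.34, and 10 were highest in that pool, where chance gives 2. For pituitary tissue in null replicate 2 the median of 13 genes was 0.45 ± 1.1 (SE), against 0.63 in wild type replicate 2, with 4 of 13 highest in null replicate 2 where chance gives 2.17. This lies under the bound of 0.5 set against that cause by less than its spread. Cga (8.32) and Tshb (8.55) were high in that pool, so the source stays open, and no biological explanation was tested.

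The hair cell median was 0.0477 over the 2 members left when dim genes were removed, too few to decide whether noise could account for the list. For Ifi27l2a, 23 interferon genes had a median of 0.08 with an adjusted p of 0.104; the bound written beforehand took any p of 0.05 or more as against a wider interferon response, which a missed threshold with an upward direction does not show, so this stays open.

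The 6 arrays make 10 splits of 3 against 3, too few for a share under 5%. For probe sets and for genes past the threshold the real split gave 0 and the highest other 1; a real count of 0 makes all 10 splits give as many whatever the data, so these counts say nothing about chance. For lists the real split gave 8 and the highest other 13, with 5 of the 10 splits, the real one included, giving as many. For probe sets with an unadjusted p under 0.01 and 1.5-fold the values were 227 and 321. There 3 of the 10 splits, the real one included, gave as many. Splits that only swap genotype within replicate numbers gave 2, 1 and 5 lists and 204, 177 and 184 such probe sets, each below the real split. These splits were singled out after the values were seen, the labels give no pairing, and they are too few to decide. The split that follows the Y-linked signal (wild type replicates 1 and 3 with null replicate 1) gave 251 such probe sets, as large as the real one, and with the Y-linked covariate the genotype fit gave 0 probe sets, 0 genes and 11 lists, of which 6 were among the 8 and the others were insulin-like growth factor, S phase, neuronal, Schwann cell and skeletal muscle genes.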
